A study of Mus musculus with 19 samples.

How the data were processed

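The series held 19 libraries from mice. Melanomas had been induced with tamoxifen in animals that carry a conditional activating Braf allele and floxed Pten. Blood of each tumor-bearing mouse was divided between a microfluidic chip coated with antibodies against CSPG4 and MCAM, here called the CTC capture (CTC, circulating tumor cells), and a chip coated with control immunoglobulin, here called the IgG capture. Primary tumors at the injection site and metastases from the back were taken from the same animals. Groups came from the labels: 5 primary tumors, 5 metastases, 4 CTC captures, 4 IgG captures and 1 skin sample from a wild-type mouse. The animal number in the labels (53, 55, 58, 72 or 73) gave the replicate. Mouse 58 had no capture library in this series. The skin sample carries the strain tag of the tumor mice in the labels, while its genotype label and the design text call it wild type; it was treated as wild type.

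Per the labels' protocols, RNA was purified on columns and sequenced on the Helicos single-molecule platform, and digital gene expression was determined as in an earlier study of the group. The values deposited by the authors are estimated counts per gene, fractional and not scaled to library size. The genome build was mm9 per the submitters' processing notes. The aligner, the counter, the gene annotation, the use of strand and the handling of reads with several matches are not given in the sources used here. Values of near-identical genes (hemoglobin chains, ribosomal proteins with pseudogenes, histocompatibility genes, keratins) and of overlapping or antisense genes are therefore uncertain. The table had 28642 rows, of which 9156 carry only a UCSC transcript identifier and 19486 a symbol or other name; 16905 of these names occur in GENCODE M21. The 10997 rows that are transcript identifiers or numbered gene models were tested and counted but not named. No coordinates are given, because the reference at hand is of a later build. All 19 value columns were matched to a sample by name, and 0 columns belonged to samples outside the series.

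Estimated counts were rounded to whole numbers. CPM values are rounded counts over the rounded total of the library, per 1e6, without further scaling. For tumor-enriched genes, shares of tumor RNA and list values in captures, hemoglobin genes and 2 abundant unnamed transcripts were left out of the totals. Because hemoglobin takes a variable share of the capture libraries, CPM of other genes are diluted there, and tested differences between groups are given as log2 fold changes from the scaled model. Ratios of low counts and folds against the floor are instead ratios of pooled CPM without that scaling. Genes were kept by filterByExpr of edgeR with a minimum count of 10. TMM scaling was applied, and the quasi-likelihood test of edgeR (glmQLFit and glmQLFTest) was run with the mouse as a block, separately for CTC against IgG (4 mice), metastasis against primary (5 mice) and CTC against primary (the same 4 mice). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The printed standard error (SE) is the absolute log2 fold change over the square root of the quasi-likelihood F statistic. It is derived from the test and is only approximate. Other means are given with the standard deviation (SD). The block was used because the design text states that blood was split and tumors were matched within a mouse. As a check of the pairing, Pearson's r of the deviations from the group means, across genes, was 0.173 to 0.411 for the 4 pairs of CTC and IgG captures, -0.106 to 0.492 for the 5 pairs of tumors and -0.0508 to 0.0767 for the 4 pairs of CTC capture and primary tumor. A mouse's own pair had a higher r than any exchanged pair in 3 of 4, 2 of 5 and 1 of 4 mice, so the expression values give weak evidence on the tumor pairs and none on capture and tumor. The Y-linked genes do not settle the pairing. Eif2s3y stood at 23.1 to 50.1 CPM in the libraries of mice 58, 72 and 73 and at 0 to 12.1 CPM in those of mice 53 and 55, with the highest of these in the CTC capture of mouse 53 (2 counts). Ddx3y stood at 1.15 to 3.69 CPM in the tumors of mice 53 and 55 but at 78.5 CPM in the CTC capture of mouse 53 (13 counts), 40.0 in the CTC capture of mouse 55 (10 counts) and 27.4 in the IgG capture of mouse 53 (10 counts), against 42.9 to 86.1 CPM in mice 58, 72 and 73. Of 32 pairs of libraries within groups, 0 differed by as little as counting noise (chi-square per degree of freedom from 2.55 to 47.3), so each was counted once.

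A set of 30 gene lists was written before the data were examined: capture and staining antigens, the engineered genes, melanocyte and pigmentation, neural crest and Schwann, MAPK output, PI3K, AKT and mTORC1 output, cell cycle, invasion and mesenchymal, Wnt signalling, fibroblast and matrix, endothelial, keratinocyte, hair follicle, sebaceous and lipid synthesis, adipocyte, skeletal muscle, erythroid, platelet and megakaryocyte, neutrophil, monocyte and macrophage, B cell, T and NK cell, mast cell, interferon response, antigen presentation, hypoxia and glycolysis, immediate early and heat shock, oxidative phosphorylation, ribosomal protein and lysosome. Some genes stand in more than 1 list. Lists with at least 5 tested members were tested with camera (limma) at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry (limma) were alternatives. Counts "adjusted over the list alone" adjust the p-values of a list's members among themselves.

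Named genes were chosen by a rule also written beforehand. For each tested comparison these were the 12 higher and 12 lower called genes with the smallest p whose difference had the same sign in every mouse; where none passed, the 5 with the smallest p in each direction, as values only; all capture and staining antigens and engineered genes; and from each other list up to 4 members with the smallest p. A selection of these is printed. For skin the rule took the 12 highest and 12 lowest differences among genes outside the range of the tumors. Exceptions, chosen after their values were seen, are Yipf1, Eif2s3y, Ddx3y, Krt5, Krt14, Krt71, Sprr1a, Col1a1, Col3a1, Igfbp5, Postn, Sparc and Tnc where single libraries or alternative settings are described, and Sox10, Plp1, Erbb3 and L1cam in the captures.

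The single skin library allows no test. Its log2(CPM + 1) was compared with the mean of the primary tumors, for genes with at least 10 CPM in skin or in that mean, and a gene was counted when skin lay outside the range of all 10 tumors and at least 4-fold from the primary mean. List medians were placed among 10000 random lists of the same size matched on expression, as a description of these libraries.

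The alternatives fixed beforehand were the fit without the block, DESeq2, limma voom with sample weights, size factors of DESeq2 or total counts alone in place of TMM, hemoglobin genes left out before scaling, no filter, a filter at a mean of 10 CPM, each mouse left out in turn, metastases in place of primaries, and other pseudocounts for skin. Leaving out the most abundant unnamed transcripts, Yipf1, or mice 53 and 55 together was added after the data were seen, as was leaving each mouse out of the marker ratios. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Simulated data were drawn gene by gene, independently, from means fitted to each mouse without the group, at the real library sizes. For CTC against primary these means average capture and tumor, so recovery there does not describe the real comparison. The procedure was tested on these data with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 5% and 80% of these for CTC against IgG (4870 genes; 10 of 95 calls false), 56% and 98% for metastasis against primary (10611 genes; 10 of 164 false), and 2% and 56% for CTC against primary (8544 genes; 1 of 59 false).

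Rounded totals ran from 165611 to 1421352 counts per library. A count of 0 was set against a floor of 3 counts, taken over the group, and ratios of low counts carry exact 95% intervals. Floors and intervals cover counting error only. Tumor-enriched genes had at least 100 CPM in the mean of the primary tumors and at most 0.05 of that in the mean of all captures, a rule that looks at the CTC captures too.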

Results

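Gene expression was measured in matched blood captures, primary melanomas and metastases of a mouse model in which tamoxifen activates Braf and deletes Pten in melanocytes. Library totals were 360062 to 1421352 counts for the 5 primary tumors, 489975 to 1355691 for the 5 metastases, 304179 to 589079 for the 4 IgG captures, 165611 to 758319 for the 4 CTC captures, and 1253618 for the skin library. The smallest library was the CTC capture of mouse 53. The captures were rich in hemoglobin transcripts. Named hemoglobin genes made up 17.6% ± 5.44 (SD, n = 4) of counts in IgG captures and 9.21% ± 4.73 (SD, n = 4) in CTC captures, against 0.00272% ± 8.74e-04 (SD, n = 5) in primary tumors. Together with 2 abundant unnamed transcripts they took 37.3% to 68.6% of counts in IgG and 8.35% to 37.7% in CTC captures. A single row, Yipf1, took 6.37% to 15.0% of the counts of each primary tumor, 4.77% to 11.1% of each metastasis, 2.74% of skin and 0.00306% to 0.0782% of each capture. The reads assigned to it were not analysed here.

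The engineered genes were detected in all 19 libraries. Pten, the phosphatase whose floxed alleles the model deletes, stood at 530 ± 97.3 CPM in primary tumors and 450 ± 119 CPM in metastases (SD, n = 5 each), at 303 ± 94.1 CPM in CTC and 188 ± 58.1 CPM in IgG captures (SD, n = 4 each), and at 344 CPM in skin. Braf, the kinase of the conditional allele, stood at 78.1 ± 38.3, 65.6 ± 23.3, 53.7 ± 21.6, 27.6 ± 13.2 and 97.3 CPM in the same order of groups. Gene-level counts do not tell recombined from intact alleles, so these values do not check the genotype.

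Tumors carried the surface antigens against which the chip was built, and the captures carried little of them. Cspg4, a surface proteoglycan of melanoma cells, stood at 278 ± 97.7 CPM in primary tumors and 197 ± 45.9 CPM in metastases, and Mcam, a cell adhesion molecule, at 308 ± 144 and 270 ± 161 CPM (SD, n = 5 each). Summed over the 4 captures of each kind, Cspg4 had 11 counts in CTC and 12 in IgG libraries, a CPM ratio of 1.02 (95% interval 0.409 to 2.53). Without mouse 53, whose CTC capture holds 6 of the 11, the Cspg4 ratio was 0.617 (0.159 to 2.14), and without mouse 72 it was 1.69 (0.617 to 4.83). Mcam had 13 and 23 counts, a ratio of 0.631 (0.294 to 1.30), which was 1.23 (0.523 to 2.87) without mouse 72 and 0.196 (0.0219 to 0.834) without mouse 73. S100b, a calcium-binding protein used for staining, had 0 counts in both, which allows up to 1.92 CPM over the CTC group. The staining antigens Mlana and Tyrp1 gave 2 and 1 counts in CTC and 1 and 0 in IgG captures, and tumors held little of them too, with 0 and 3 counts over the primary tumors of the same 4 mice. Sox10, a transcription factor of the neural crest, had 0 counts in CTC and 11 in IgG captures, 10 of them in the IgG capture of mouse 72. Plp1, a myelin protein, had 11 and 21 counts, a ratio of 0.585 (0.255 to 1.27), which was 1.07 (0.331 to 3.38) without mouse 72. Erbb3, a receptor of the neural crest lineage, had 5 and 5. These ratios use full totals, of which hemoglobin takes a larger share in IgG captures, so they are shifted toward CTC. On that scale Pten had a ratio of 1.72 (1.49 to 1.99), against a log2 fold change of 0.14 in the scaled model. Totals without hemoglobin and 2 abundant unnamed transcripts gave the capture and staining antigens 25.5 CPM in pooled CTC and 43.7 in pooled IgG captures. Without mouse 72 these were 32.0 and 33.1 CPM.

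**Figure D1:**
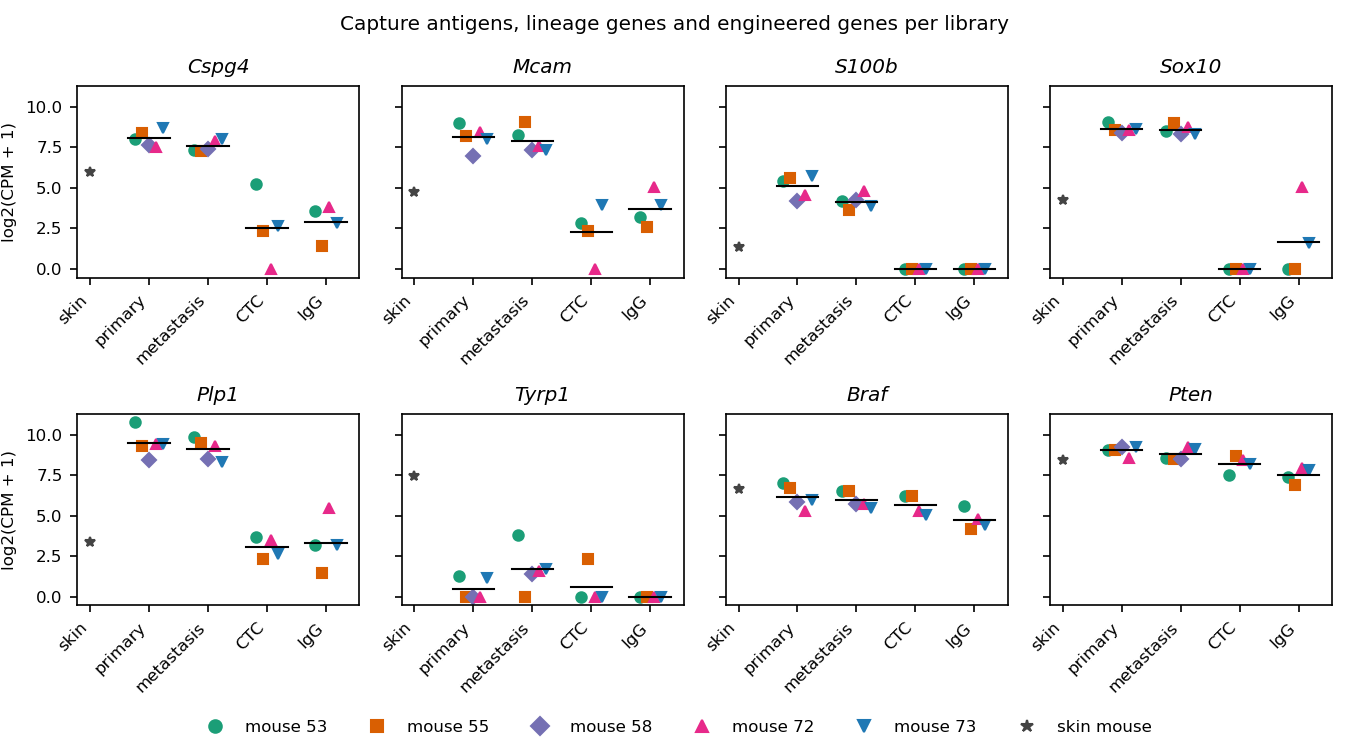
Each point is a library; the vertical axes give log2(CPM + 1) of a capture or staining antigen, a lineage gene or an engineered gene, the horizontal axes the group, and black lines the group means on that scale. Cspg4, Mcam, S100b, Sox10 and Plp1 sit lower in the 4 CTC and 4 IgG captures than in the 10 tumors, and Sox10 reaches 32.9 CPM in the IgG capture of mouse 72.

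The comparison of CTC with IgG captures addresses which transcripts the antibody-coated chip enriches from the same blood. Red cell transcripts were lower in CTC captures: all 14 tested erythroid genes had negative values, with a median log2 fold change of -1.49 (camera adjusted p = 6.79e-17). Examples are Snca (-1.80, SE 0.57), the anion exchanger Slc4a1 (-1.49, SE 0.52), the heme synthesis enzyme Fech (-1.42, SE 0.50) and the erythroid transcription factor Klf1 (-1.15, SE 0.38). This list call was lost with an estimated correlation (p = 0.0692, adjusted p = 0.831). Monocyte and macrophage genes were higher, with 19 of 20 positive and a median of 0.58 (adjusted p = 1.19e-05; p = 0.279 with an estimated correlation). Among them were the transcription factor Mafb (1.19, SE 0.34), the growth factor receptor Csf1r (0.96, SE 0.49) and Ly6c2 (0.67, SE 0.29). Platelet genes had 12 of 14 positive values and a median of 0.30 (adjusted p = 0.0182; p = 0.355 with an estimated correlation), with Cd9 at 0.93 (SE 0.30) and Gp9 at 0.71 (SE 0.32). Lysosomal genes had 17 of 18 positive values and a median of 0.34 (adjusted p = 0.0229; p = 0.449 with an estimated correlation), with the cholesterol transporter Npc2 at 0.73 (SE 0.47) and Lamp2 at 0.49 (SE 0.38).

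No single gene passed the edgeR quasi-likelihood test between CTC and IgG captures. Of 4870 genes, 0 were called at an adjusted p under 0.05, while 203 had an unadjusted p under 0.05 and 244 would by chance; limma voom called 0. DESeq2 called 16, of which 1 was higher, the small GTPase Rac1 (0.99, DESeq2 adjusted p = 0.0447), and 15 were lower. The lower ones included the amino acid transporter Slc7a5 (-1.60, DESeq2 adjusted p = 9.65e-04), Snca, Slc4a1, Fech and the interferon-induced exonuclease Isg20 (-1.32, DESeq2 adjusted p = 0.0447). By edgeR the genes with the smallest p were, with positive values, Zfp384 (1.20, SE 0.32), Mafb, Rac1 (1.01, SE 0.30), Gpr35 (0.97, SE 0.29) and Acox3 (0.98, SE 0.30), and with negative values Yod1 (-1.65, SE 0.32), Slc7a5 (-1.58, SE 0.33), Ptdss2 (-1.41, SE 0.34), D16Ertd472e (-1.21, SE 0.29) and Akap12 (-1.29, SE 0.34), each with an adjusted p of 0.9997. Pten (0.14, SE 0.30) and Braf (0.42, SE 0.28) did not pass. Adjusted over the list alone, 1 gene passed, Slc7a5 in the PI3K, AKT and mTORC1 list. With no filter on low counts 5 genes were called, all lower in CTC: Col1a1, Col3a1, Igfbp5, Postn and Sparc, whose counts come mostly from the IgG capture of mouse 72.

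Of the 15 lists tested between captures, 11 were not called, with adjusted p from 0.0602 (neutrophil) to 0.998 (antigen presentation). The other 15, among them the neural crest and Schwann list with 4 tested genes and the capture antigens with 0, were too small for a set test. The differences were uneven between mice: the mean log2 difference of erythroid genes was -2.19 in mouse 53, -2.50 in mouse 55, -0.65 in mouse 73 and -0.14 in mouse 72. It was for monocyte and macrophage genes 2.06 in mouse 73 and -0.35 in mouse 53. Without mouse 73 the monocyte and macrophage call was lost (adjusted p = 0.672) and 2 lists were called in place of 4; without mouse 53, 10 were called. The platelet call was lost without mouse 72 (adjusted p = 0.547) and the lysosomal one without mouse 55 (0.0984) or mouse 73 (0.948), with no filter on low counts (0.0550) and with a filter at a mean of 10 CPM (0.0538). Total counts in place of TMM moved the median of all genes by 0.53, and the 4 calls kept their direction relative to the other genes.

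**Figure D2:**
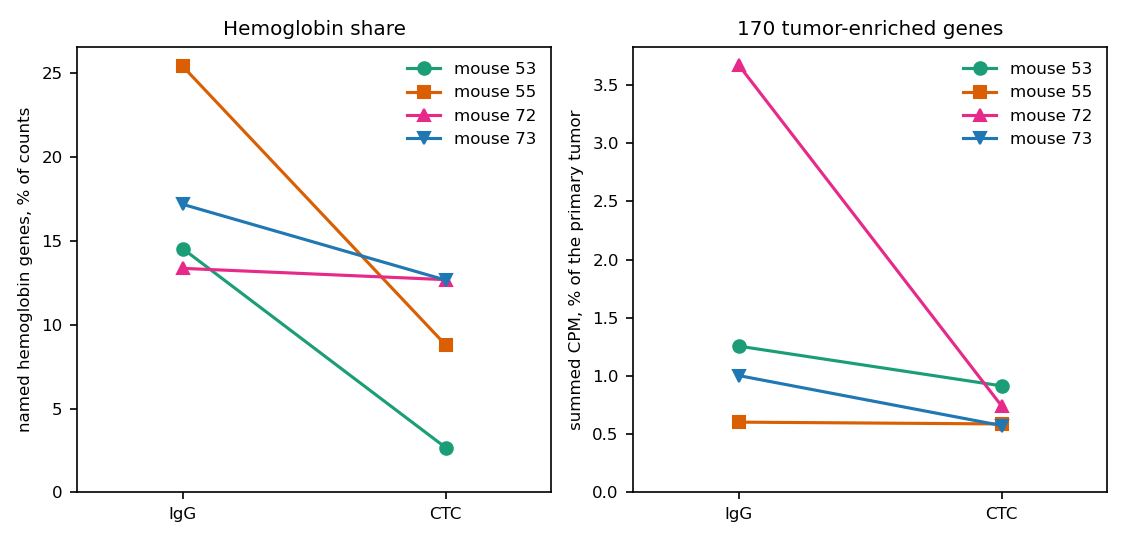
Lines join the IgG and CTC captures of a mouse. The left axis gives the share of counts in named hemoglobin genes in percent. The right axis gives the summed CPM of 170 tumor-enriched genes in percent of the same mouse's primary tumor. For these sums, hemoglobin genes and the most abundant unnamed transcripts were left out of the library totals, so they are not CPM on full totals. Hemoglobin took 13.4% and 12.7% in mouse 72 but 25.4% and 8.80% in mouse 55, and the tumor-enriched sum was highest in the IgG capture of mouse 72, at 3.67%, or 7.64% without Yipf1, which makes up 58.3% of the sum in that primary tumor.

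Metastases were compared with the primary tumors of the same mice. Cell cycle genes were higher in metastases, with 15 of 16 tested members positive and a median log2 fold change of 0.56 (camera adjusted p = 1.28e-06; p = 0.0686 with an estimated correlation), and 6 of them passed when adjusted over the list alone. The thymidylate synthase Tyms (0.87, SE 0.24) was higher in 5 of 5 mice, and Cenpf (1.08, SE 0.31) and the proliferation marker Mki67 (1.09, SE 0.34) in 4 of 5; Top2a stood at 1.32 (SE 0.41), higher in 3 of 5. Interferon response genes had 18 of 20 positive values and a median of 0.30 (adjusted p = 7.81e-04; p = 0.174 with an estimated correlation), such as Mx1 (1.46, SE 0.42), Stat1 (0.47, SE 0.17) and Isg15 (0.70, SE 0.28). Antigen presentation genes had 12 of 13 positive values and a median of 0.33 (adjusted p = 0.00536; p = 0.136 with an estimated correlation), such as the class II transactivator Ciita (0.96, SE 0.40) and H2-Eb1 (0.62, SE 0.28).

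MAPK output genes, which respond to signalling downstream of Braf, were lower in metastases, with 12 of 16 negative and a median of -0.40 (adjusted p = 7.81e-04; p = 0.0589 with an estimated correlation). The feedback inhibitor Spry4 (-0.69, SE 0.16) was lower in 5 of 5 mice, and Etv1 (-0.77, SE 0.28) and Dusp4 (-0.84, SE 0.33) in 4 of 5; 1 member passed when adjusted over the list alone. Neural crest and Schwann genes had 14 of 17 negative values and a median of -0.31 (camera adjusted p = 0.00175, or p = 0.143 with an estimated correlation). Examples are Gfra1 (-0.88, SE 0.30) and Foxd3 (-0.40, SE 0.16). The summed CPM of this list was lower in the metastasis in mice 53, 58 and 73. It was higher there in mouse 55 (4006 against 3812) and mouse 72 (3798 against 3422). All 5 list calls between tumors had an adjusted p of 0.571 with an estimated correlation. Fibroblast and matrix genes, not called (adjusted p = 0.110), had 18 of 24 positive values and a median of 0.21. Their mean difference was 0.51 in mouse 53 and 0.65 in mouse 73, where MAPK output (-0.55, -0.52) and neural crest genes (-0.52, -0.70) had their lowest means, and -0.55 to 0.29 in the other 3 mice. Fry called only the PI3K, AKT and mTORC1 list (adjusted p = 8.00e-04, 14 of 20 negative), in which the stress-induced mTORC1 inhibitor Ddit4 (-0.92, SE 0.22) alone passed adjusted over the list alone. Camera did not call that list (adjusted p = 0.110). It holds the inhibitor Ddit4 beside kinase genes such as Akt1, so its direction does not measure pathway output.

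Single genes did not pass between metastases and primaries. Of 10611 genes tested by edgeR, 0 were called, with 842 at an unadjusted p under 0.05 where 531 would be by chance. Voom called 0, and DESeq2 called 1, the complement component C3 (-1.35, DESeq2 adjusted p = 0.0101). The smallest edgeR p-values belonged, on the lower side, to the collagen Col28a1 (-1.44, SE 0.22, adjusted p = 0.488), C3 (-1.36, SE 0.25), Gda (-0.92, SE 0.17), Cpe (-0.92, SE 0.17) and Neto1 (-1.06, SE 0.22). On the higher side they belonged to Pnpla1 (1.36, SE 0.28), Tnfrsf10b (0.82, SE 0.18), Rgs9 (0.88, SE 0.19), Ckap2l (1.94, SE 0.43) and Pdgfrl (1.07, SE 0.24). Each of these 10 had its direction in 5 of 5 mice. Of the antigens, S100b (-1.18, SE 0.34; lower in 3 of 5 mice, higher in 2) passed adjusted over the 3 tested genes of the list alone but not over all genes, and Cspg4 (-0.50, SE 0.22) and Mcam (-0.24, SE 0.27) did not pass. Pten (-0.27, SE 0.22) and Braf (-0.25, SE 0.18) did not pass either. With no filter on low counts 221 genes were called (157 higher, 64 lower). With a filter at a mean of 10 CPM 5 were called, all higher: the epidermal and hair genes Krt5, Krt14, Krt71 and Sprr1a and 1 unnamed transcript.

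The remaining 18 of 23 lists tested between tumors were not called by camera, with adjusted p from 0.0979 (immediate early and heat shock) to 0.957 (T and NK cell). For the melanocyte, adipocyte, endothelial and ribosomal lists the median and the mean differed in sign, and for skeletal muscle both were positive while the test pointed down. Skeletal muscle genes differed by 3.03 in mouse 73 and by -2.60 in mouse 55 (mean log2 difference), and Trp63, a keratinocyte transcription factor, had a value of 1.86 (SE 0.76), or 0.46 without mouse 53, whose metastasis held 258 counts of it. Adjusted over the list alone, 1 gene was higher and 1 lower in both the neutrophil list (4 tested genes) and the T and NK cell list (5). The B cell (4 tested), mast cell (3), keratinocyte (2) and hair follicle (2) lists had 0. Krt5 was removed by the main filter, so it is not among the tested keratinocyte genes. It was higher in the metastasis of each mouse. Its CPM there was 523 in mouse 53, 40.8 in mouse 73, 31.35 in mouse 58, 9.34 in mouse 55 and 2.04 in mouse 72. In primary tumors it stood at 0 to 2.81 CPM. Without mouse 72 the interferon call was lost (adjusted p = 0.310), and so was that of antigen presentation (0.0704), which was also lost without mouse 55 (0.295) and with no filter on low counts (0.279). By limma voom the interferon call was lost as well (0.0636). The number of lists called was 3 without mouse 72, 9 without mouse 55 and 10 without mouse 73.

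**Figure D3:**
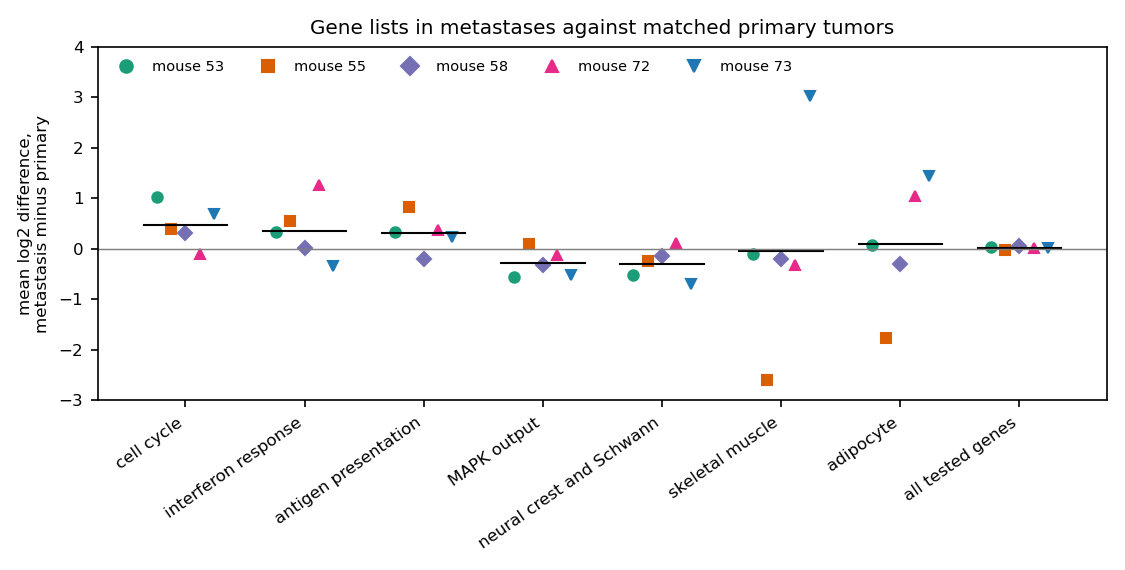
Each point is the mean log2 difference, metastasis minus primary, of a gene list in a mouse, and black lines are means over the 5 mice; the list names stand on the horizontal axis. Cell cycle genes lie above 0 in 4 of 5 mice, from -0.10 to 1.04, and skeletal muscle genes spread from -2.60 to 3.03.

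CTC captures differed widely from the primary tumors of the same mice. Of 8544 genes tested by edgeR, 3245 were called, 1421 higher and 1824 lower in CTC, and 3127 of them had the same sign in 4 of 4 mice. Blood cell transcripts rose in the captures: all 14 tested erythroid genes (median log2 fold change 5.66), all 13 neutrophil genes (4.54), 10 of 11 B cell genes (mean 4.40), 12 of 16 platelet genes (2.57) and 16 of 17 antigen presentation genes (2.21). All 5 list calls were lost with an estimated correlation, with adjusted p = 0.122 for erythroid, 0.194 for B cell and 0.203 for the other 3 (before adjustment p = 0.00511, 0.0677, 0.0162, 0.0261 and 0.0450, in the order above). Transcripts of tumor and stroma fell: 21 of 22 fibroblast and matrix genes (median -7.39) and 12 of 15 neural crest and Schwann genes (-6.08, or -6.07 with genes at 0 counts set at their bound), with p = 0.0647 and 0.0555 with an estimated correlation.

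Among the genes that rose were the red cell genes Slc4a1 (6.88, SE 0.45, adjusted p = 3.36e-05), Car2 (7.00, SE 0.47), Snca (6.89, SE 0.51) and Alas2 (8.96, SE 0.71). The neutrophil collagenase Mmp8 (6.62, SE 0.47) and Bst1 (4.54, SE 0.41), the B cell receptor component Cd79a (7.99, SE 0.66) and the B cell antigen Ms4a1 (6.62, SE 0.52) rose as well. Of the platelet genes, Nrgn rose by 6.47 (SE 0.50), the chemokine Ppbp was 728-fold higher (95% interval 201 to 6023, against 2 counts in the 4 primary tumors) and the platelet tubulin Tubb1 504-fold (89.5 to 19990, against 1 count). Further genes with the smallest p were Fam46c (6.37, SE 0.46), the integrin Itgal (5.84, SE 0.43), Plac8 (5.41, SE 0.41), Klf2 (6.32, SE 0.49) and Clec4a3 (4.98, SE 0.39). Monocyte and macrophage genes went both ways, with 16 higher and 6 lower of 27 (median 1.89; p = 0.190 with an estimated correlation); Ccr2 (4.90, SE 0.46), the cathepsin Ctss (3.95, SE 0.40) and Ly6c2 (5.31, SE 0.44) rose. The class II genes H2-DMb1 (5.08, SE 0.40) and H2-Aa (3.83, SE 0.44) rose. So did 10 of 18 immediate early and heat shock genes (median 1.71; p = 0.280 with an estimated correlation), such as Fos (3.67, SE 0.46) and Zfp36 (3.67, SE 0.47), and 17 of 32 ribosomal protein genes (median 1.24; p = 0.405 with an estimated correlation), such as Rplp0 (1.97, SE 0.40) and Rpl19 (2.12, SE 0.41), with 1 lower. Of 15 interferon response genes 5 rose and 1 fell (median 0.96; p = 0.129 with an estimated correlation), among them Isg20 (7.25, SE 0.57) and Rsad2 (5.00, SE 0.40).

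Matrix genes led the transcripts that fell. Col1a1, the main collagen of connective tissue, had 14500 counts in the 4 primary tumors and 1 count in the 4 CTC captures, a ratio of 6475 (95% interval 1162 to 255800). Bgn (-9.11, SE 0.69), Sparc (-8.70, SE 0.67), Hspg2 (-8.59, SE 0.62) and Sparcl1 (-8.43, SE 0.65) fell, as did the basement membrane collagen Col4a1 (-7.34, SE 0.55) and Kank4 (-6.61, SE 0.51). With 1 to 3 counts in CTC, Col4a2 was 3097-fold lower (556 to 122300), Prelp 609-fold (109 to 24090), Col6a1 490-fold (167 to 2376), Col16a1 305-fold (84.2 to 2517) and Igfbp5 268-fold (91.5 to 1300). Of the lineage genes, Plp1 fell by 6.41 (SE 0.50) and the cadherin Cdh19 by 6.08 (SE 0.56). Sox10 was at least 232-fold and S100b at least 22.8-fold lower in CTC, each against the floor of 3 counts; the exact 95% lower limits, which allow for more than the floor, are 188 and 18.3. The capture antigens Mcam (-5.26, SE 0.65, adjusted p = 1.58e-04) and Cspg4 (-4.96, SE 0.72, adjusted p = 3.93e-04) fell too, so 3 of 3 tested antigens were lower. Pten (-0.43, SE 0.38) and Braf (-0.27, SE 0.32) did not pass.

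Other lists that fell in CTC captures were skeletal muscle with 10 of 10 genes (median -4.27; Acta1 -5.33, SE 0.47) and Wnt signalling with 7 of 10 and 1 higher (median -1.90; Sfrp1 -4.89, SE 0.47). So did invasion and mesenchymal with 15 lower and 5 higher of 25 (median -1.49; Mmp14 -5.02, SE 0.46; Loxl2 -4.69, SE 0.43), and MAPK output with 6 of 14 (median -0.88; Spry1 -4.90, SE 0.50; Ccnd1 -4.56, SE 0.51). With an estimated correlation these 4 had p = 0.160, 0.223, 0.0631 and 0.0994, in that order. Camera called 15 lists of 24, 9 higher and 6 lower, with adjusted p from 2.68e-20 (fibroblast and matrix) to 0.0145 (Wnt signalling). None of the 15 calls held with an estimated correlation, where the adjusted p ran from 0.122 (erythroid) to 0.526 (ribosomal protein), and fry called 18. The Wnt call was also lost without mouse 72 (adjusted p = 0.0537). The lists for PI3K, AKT and mTORC1 output (3 of 19 genes higher, among them Slc7a5 at 2.67, SE 0.40), cell cycle (2 of 9 higher), endothelial (6 of 10 lower, 1 higher), melanocyte (2 of 6 lower, 1 higher), sebaceous and lipid synthesis (3 of 8 higher, 1 lower), adipocyte (2 of 6 higher, 1 lower), hypoxia and glycolysis (5 of 19 higher, 3 lower), oxidative phosphorylation (5 of 21 higher) and lysosome (4 of 21 higher, 2 lower) were not called, with adjusted p from 0.0582 to 0.666. For the adipocyte list the median (0.31) and the mean (-0.19) differed in sign. Among lists too small to test, 1 of 1 keratinocyte and 1 of 2 hair follicle genes were lower, and 0 of 3 T and NK cell genes and 0 of 1 mast cell genes passed.

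The number of genes called between CTC captures and primary tumors was 2147 without mouse 55 and 2095 without mouse 73. With total counts in place of TMM, which moved the median of all genes by -0.35, 1011 genes were higher and 2358 lower, so the higher share of calls was 30.0% in place of 43.8%.

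Skin from a wild-type mouse was set beside the tumors without a test, since there was 1 library. Of 12720 genes at the level used, 7414 (58.3%) lay outside the range of the 10 tumors, where chance gives 18.2%, and 2007 of these also differed by at least 4-fold from the primary mean, 1097 higher and 910 lower in skin. The inner root sheath keratin Krt71 stood at 8648 CPM in skin and 3.02 ± 3.26 CPM in primary tumors (SD, n = 5), the keratinocyte keratin Krt5 at 2645 against 1.08 ± 1.17 CPM, and Krtap3-1, a hair keratin-associated protein, at 3097 against 0.712 ± 1.24 CPM. All 27 hair follicle genes (median log2 difference 8.76) and 22 of 23 keratinocyte genes (7.64) were higher in skin than in any tumor. So were 17 of 23 melanocyte genes (1.63), 24 of 28 cell cycle genes (1.88), 31 of 32 ribosomal protein genes (1.59), 9 of 12 sebaceous (2.42) and 9 of 12 adipocyte genes (2.49). Each of these medians lay at or above percentile 99.99 of random lists. Neural crest and Schwann genes were lower, with 15 of 18 below all tumors (median -2.94). Plp1 stood at 9.57 CPM in skin and 814 ± 528 CPM in primary tumors, Cdh19 at 3.19 against 253 ± 112 CPM. Fibroblast and matrix genes had 15 of 24 below all tumors (median -1.13, percentile 2.12). Tumors also exceeded skin in the collagen Col20a1 (1723 ± 417 against 2.39 CPM), the potassium channel gene Kcna1 (1031 ± 510 against 9.57 CPM) and Spp1 (267 ± 222 against 0.798 CPM). The count of 2007 genes became 878 (563 higher, 315 lower) with a pseudocount of 10.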

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

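Chosen only after the result was seen were the choice of tumor-enriched genes without CTC, the tests of the hemoglobin share and of red cells, the exchange of the labels of mouse 72, and the splits for the gene counts between captures and between tumors; the other tests were set beforehand. Of 184 groups of 4 or 5 values, 19 had a library or mouse whose gap to its nearest neighbor was large against the group's range (Dixon's 95% critical value), where chance gives about 1 in 20 groups, or 9.

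The IgG capture of mouse 72 stood apart in 4 measures: Sox10 at 32.9 CPM (nearest other 2.07), Plp1 at 42.7 CPM (8.26), Yipf1 at 0.0782% of counts (0.00620) and the fibroblast and matrix list at 2926 CPM (302). That list value leaves hemoglobin and 2 abundant unnamed transcripts out of the total, while the values beside it use the full total. The CTC capture of mouse 53 had Cspg4 at 36.2 CPM (5.28), from 6 counts. In the difference between CTC and primary, mouse 53 stood apart for Cspg4 (-2.32, nearest -5.29), Rpl19 (0.96, nearest 2.39), the fibroblast and matrix list (-5.14, nearest -6.19) and the ribosomal protein list (0.00682, nearest 1.41). Sox10 met the same rule there (-7.28, nearest -6.86), but with 0 counts in all 4 CTC captures these values are set by the prior count, library size and the primaries, and say nothing of the captures. In the same difference mouse 72 stood apart for Braf (0.34, nearest -0.41), Col4a2 (-7.91, nearest -9.05) and the platelet list (3.56, nearest 2.43). Between captures, Cd9 was 1.52 in mouse 72 (nearest 0.69) and Akap12 was -0.30 in mouse 53 (nearest -1.24). Among tumors, the primary of mouse 53 had Plp1 at 1725 CPM (696), and its metastasis had Krt5 at 523 CPM (40.8), Tyrp1 at 13.3 CPM (2.26) and the keratinocyte list at 1989 CPM (370).

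Erythroid genes lay lower in CTC than in IgG captures. Counts taken by hemoglobin, whose share was higher in IgG in 4 of 4 mice, would lower other genes in IgG and so point the other way; leaving out hemoglobin and the most abundant unnamed transcripts (median -1.42) therefore tests nothing. Fewer red cells as the only difference is argued against in mouse 73 alone, where the monocyte, neutrophil and B cell lists parted by 2.997. In mice 53 and 55, which had the largest erythroid differences, these lists parted by 0.43 and 0.78, and in mouse 72 by 0.62. The 0.43 of mouse 53 lay within the bound written for this cause. Without mouse 73 no spread exceeds 1, so the argument rests on 1 mouse and the cause stays open for the others. Different retention of several blood cell types on the chips may account for the pattern, which no independent measurement in the series tests.

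No rise of tumor markers in CTC over IgG captures was detected. Summed over 170 tumor-enriched genes, CPM without hemoglobin in the totals was higher in CTC in 0 of 4 mice. Full totals, which hemoglobin fills more in IgG captures, would shift these sums toward CTC. The count met the value set beforehand against tumor cells with other tumor transcripts. However, those genes were chosen as low in the mean of both captures, which can drop genes that tumor cells raise. Chosen without CTC, the sum was higher in 2 of 4 mice (from IgG alone) or 1 of 4 (from IgG of the other mice). That 1 is mouse 55, with 947.25 against 946.93 CPM. Genes chosen as low in IgG alone favor CTC. These counts also meet the value set beforehand, 2 or fewer mice. The question is left open by a condition, equal counts under each choice, that was added after the counts were seen. Too few reads stays open. The upper limit of tumor RNA from the neural crest list, 14.5%, passed the 5% set beforehand for this cause. It is set by background (Cnp, Mbp and L1cam are expressed in the captures) and so decides nothing. Setting the limit aside for background was not among the conditions written beforehand. With nothing subtracted, the capture and staining antigens gave an upper limit of 5.06%. For Cspg4, Mcam, S100b, Sox10, Plp1 and Erbb3, primary tumors exceeded pooled CTC captures by lower limits of 18.3-fold (S100b) to 188-fold (Sox10), on full totals. Sox10, Plp1 and Erbb3 were picked after their values were seen, and these limits cover counting error only. The pooled difference of the neural crest list over IgG, with hemoglobin left out of the totals, had an upper limit of 1.09% of the primary level. That limit was 3.82% without mouse 72, 5.56% without mouse 73 and -4.88% without mouse 53. The limits cover counting error and not the spread between mice. Single mice gave 17.3% (mouse 53, 13.51 to 21.03), 1.55% (mouse 55), -15.5% (mouse 72) and -7.71% (mouse 73). All lay outside the pooled interval of -2.53% to 1.09%, which therefore sets no bound on the share of tumor RNA. In mouse 53, 180 of the neural crest list's 217 counts came from L1cam. Exchanged labels in mouse 72 could account for the tumor transcripts in its IgG capture, but its erythroid difference of -0.14 lies between the values that would decide, so this cannot be told apart.

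Cell cycle genes lay higher in metastases than in primaries. Skin like that of the 1 skin library, where these genes are at 1335 CPM, is argued against. In 4 of 4 mice with a rise the estimated share of skin was under 0.5 of that needed (14.5% against 45.1% in mouse 53, at most 1.38% against 14.5% to 25.0% in mice 55, 58 and 73). Both shares assume the make-up of that library. The metastasis of mouse 53 had Krt5 at 523 CPM but Krt71 at 2.95 CPM, where skin had 2645 and 8648, so its share is uncertain. Faster proliferation in metastases may account for the rise, as a hypothesis not tested here.

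Chance is not excluded for the lists between captures. As many lists as the real 4 were called in 26 of 32 splits of the capture libraries, with 8 at most. Of the 8 splits that part every mouse, 6 called as many. Splits other than the real one called 5 lists at the median, more than the real 4. For genes the real count is 0, which 32 of 32 splits must match, so the splits say nothing there. Chance is not excluded for the lists between tumors either. There 82 of 100 splits of the tumor libraries called as many lists as the real 5, with 12 at most. Of the 14 that part every mouse, 11 called as many. Tumor splits other than the real one called 7 lists at the median, more than the real 5. The real gene count of 0 is matched by 100 of 100 splits by necessity (highest other 5), so it says nothing about chance. For CTC against primary, 1 of 32 splits, the real one, gave as many as 3245 genes, and the highest other gave 0, a share under 0.05. Of the 8 splits that part every mouse, as the paired design does, 1 gave as many, and 8 are too few for such a share. The number of lists does not set the real split apart: 8 of 32 splits gave as many as the real 15, with 19 at most (2 of the 8 that part every mouse). Other splits called 11 lists at the median, so this number says little about single lists, of which erythroid (mean difference 4.74 to 5.67), fibroblast and matrix (-6.24 to -5.14) and neural crest (-4.21 to -3.79) had the same sign in 4 of 4 mice.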

How the results depend on the processing

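Chosen after seeing the data were leaving out the most abundant unnamed transcripts, Yipf1, mice 53 and 55 together, and each mouse from the marker ratios and tumor shares. Of the gene counts under alternatives, 36 stayed within 1.5 times the reported count and 7 moved. Between captures and between tumors the main test called no gene, so a count there could stay only where the alternative also called none. Such matches do not measure stability. Of the list counts, 33 stayed and 13 moved. Of the called lists, 329 results kept direction and call and 46 lost the call; of the named genes, 1542 kept their side of the threshold and 25 came to pass it (6 between captures and 1 between tumors by DESeq2, 18 between tumors with no filter). None of these changed direction. The cause was not tested for the changes below, except that leaving out mice reduces the samples.

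With no filter on low counts 5 genes were called between captures, and 221 genes and 13 lists between tumors. A mean of at least 10 CPM gave 5 genes and 8 lists between tumors. DESeq2 called 16 genes between captures and 1 between tumors. With an estimated correlation 0 lists were called in each of the 3 comparisons. Fry called 0 between captures and 1 between tumors. Without mice 53 and 55, 10 lists were called between captures, and the erythroid median was -0.38. A pseudocount of 10 gave 878 genes for skin.

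Leaving out each mouse in turn gave 0 genes and 2 (without mouse 73) to 10 lists (without mouse 53) between captures. Between tumors it gave 0 genes and 3 (without mouse 72) to 10 lists (without mouse 73). For CTC against primary it gave 2095 (without mouse 73) to 4705 genes (without mouse 53) and 15 to 16 lists. The 0 gene calls are by edgeR; the counts at unadjusted p and by the other tools stand with each comparison.

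Without the block for the mouse, 0 genes and 4 lists were called between captures, 0 genes and 5 lists between tumors, and 3908 genes (1835 higher, 2073 lower; 3215 shared with the blocked fit) and 16 lists between CTC captures and primary tumors. Pseudocount alternatives for the count tests were not run. At these depths 4870 genes could be tested between captures, 8544 between CTC captures and primaries and 10611 between tumors, and simulated 2-fold changes were recovered at 5%, 2% and 56%; the comparisons also differ in mice and in spread, so depth was not separated from these.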

Other observations

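The correlation in this part was chosen only after the result was seen, and the values stand without explanation. Skin also exceeded all 10 tumors in 17 of 24 immediate early and heat shock genes (median log2 difference 1.37), 21 of 29 oxidative phosphorylation genes (0.91) and 10 of 15 Wnt signalling genes (1.33), and lay below all tumors in 14 of 25 monocyte and macrophage genes (-1.16). The pigment genes Mlana and Tyrp1 stood at 27.1 and 172 CPM in skin, against 0 and 0.518 ± 0.713 CPM in primary tumors (SD, n = 5).

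The IgG capture of mouse 72 held 98 counts of Col1a1, 88 of Postn, 109 of Tnc, 84 of Sparc, 72 of Igfbp5 and 46 of Col3a1, where no other capture held more than 1, 2, 7, 10, 2 and 3. Relative to the primary tumor of mouse 72 their CPM ran from 4.56% (Col3a1) to 54.9% (Tnc), while Col20a1 stood at 0.456%, so the profile is not an even dilution of that tumor. Over the 170 tumor-enriched genes, the excess in this library had a Spearman rho of 0.471 to 0.696 with the 10 tumors, highest for the metastasis of mouse 55. The primary tumor (0.609) and metastasis (0.534) of mouse 72 lie within the range of the other tumors; rho is across genes and not replicates. These genes were chosen after their values were seen.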
